A study of Mus musculus with 2 samples.

How the data were processed

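The deposited values were whole-number UMI counts per cell and gene, with 1 table per library and no scaling. Per the file headers, they came from the BD Rhapsody whole-transcriptome analysis pipeline, version 1.8, with a mouse STAR index; whether the molecule counts carried that pipeline's error correction is not given in the sources used here. The submitters' processing notes name mouse genome build mm10 and Seurat, and the sources used here do not say what Seurat was used for. Both tables ended inside their last line, which left 1 incomplete cell per library; those cells were dropped. The tables may thus be incomplete and may lack the shallower cells of each library; the size of every difference in class shares depends on this. Cells ran from deep to shallow down each table. The median fell from 23571.5 UMIs in the first 10% of the WT cells to 7176.5 in the last 10%, and from 30193.5 to 12258 in the Mettl3pKO cells. Cells shallower than the last one in each table were not analysed here, and the lowest total was 3803 UMIs in WT and 10719 in Mettl3pKO. The tables listed 23515 and 23775 genes, of which 22023 were in both; genes in only 1 table held 1690 UMIs in WT and 1182 in Mettl3pKO and were left out.

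Cells with at least 200 genes and at most 25% mitochondrial UMIs were taken. Scrublet, run per library, marked 338 of 6372 WT cells (5.30%), which were removed, and 1 of 3623 Mettl3pKO cells (0.0276%), so that it did not work on Mettl3pKO and doublets remain there. The 6034 WT and 3622 Mettl3pKO cells kept were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes, without globin, mitochondrial, ribosomal protein and sex-linked genes, gave 30 principal components, 15 nearest neighbours and 30 Leiden clusters at resolution 1.0, with no integration of the libraries. Each cluster took the class whose markers, out of 21 marker lists, stood highest on average between their lowest and highest cluster means, provided 3 or more of them reached 0.1 UMIs per 10000; classes are called X-like and need not be those of the submitters. Clusters with a median doublet score above 0.1 stayed unnamed. This scoring and that threshold were set after the values were seen, whereas the marker lists were not. The 7 pancreatic epithelial classes, acinar-like, duct and trunk-like, endocrine progenitor-like, Fev precursor-like, alpha-like, beta-like and delta-like, formed the epithelial denominator.

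Gene levels are UMIs of the gene per 1000000 UMIs of the class (CPM), from UMIs summed per library and class. A ratio of Mettl3pKO to WT carries an exact conditional binomial 95% interval, a single level an exact Poisson one, and a share of cells an exact Clopper-Pearson one. With 1 library per genotype no test was made, and these intervals cover counting error only. A count of 0 was read as allowing up to 3 counts. Log2 ratios were computed with 0.5 UMIs added. Shares of cells with a UMI were compared after each cell was thinned to 7812 UMIs, the 10th percentile of WT epithelial cells; shallower cells were left out. A cell was called proliferating with 2 or more UMIs over 9 genes (Mki67, Top2a, Cdk1, Ccnb1, Ube2c, Birc5, Tpx2, Cenpf and Aurkb).

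The class markers, 29 gene lists, the filters and the naming rule were fixed before the data were examined. The rule took, per class, Mettl3 and then, among genes with at least 100 CPM in either library and at least 50 UMIs over both, the 12 with the highest and the 12 with the lowest Mettl3pKO/WT ratio, ranked by the interval bound nearest 1. Mitochondrial, ribosomal protein, globin and sex-linked genes were left out, as were acinar enzymes and islet hormones outside their own classes. From each list described, the rule took 2 to 4 members with the ratio farthest from 1. Some items it named are not reported here, and counts of named genes over the alternatives leave them out. A list is described by its members with at least 20 UMIs, the number at least 1.5-fold higher or lower, its median log2 ratio, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of expression level. Only classes with 30 or more cells in both libraries were compared, which left endocrine progenitor-like, Fev precursor-like, delta-like and endothelium-like cells without expression ratios.

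On simulated libraries with the real depths and 200 changed genes in each of 5 classes, 94.7% to 96.1% of the intervals held the true ratio. All 24 genes named per class were changed ones. The simulated class sums were Poisson counts, the model behind the intervals, with no spread between cells or libraries. They check the computation and not whether the intervals cover the spread of real cells. Alternatives covered the filters, doublets, clustering, class assignment, scaling, depth and thresholds. After the data were seen, others were added: cells of 13000 UMIs or more in both libraries (a common floor), the top 5% of doublet scores removed for ratios and proliferation, and cells split by UMIs of Xist or of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. That split used UMIs without thinning. Another scaling used TMM factors from edgeR; it moved log2 ratios by -0.12 in acinar-like cells and by 0.19 over all epithelial cells. Gene positions are from GENCODE vM21 on mm10. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.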

Results

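Pancreas cells of mouse embryos at stage E15.5 were profiled by single-cell RNA sequencing from wild-type embryos (WT) and from embryos whose Pdx1+ pancreatic progenitors lack Mettl3 (Mettl3pKO). Mettl3 is the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) on RNA. There was 1 library per genotype, so that no difference below has a replicate check. The tables may lack the shallow cells of both libraries, so that every share below is one of the cells held. The WT library held 6384 complete cells and 80011421 UMIs, with a median of 10824 UMIs and 3528.5 genes per cell. The Mettl3pKO library held 3624 complete cells and 65779771 UMIs, with medians of 16481 UMIs and 4360.5 genes. Mettl3pKO cells were deeper in each of the 7 epithelial classes: the medians were 11517 UMIs in WT and 16758 in Mettl3pKO for epithelial cells together, and 8779.5 and 14634 for endocrine progenitor-like cells. The median share of mitochondrial UMIs was 6.87% in WT and 9.41% in Mettl3pKO. Several values below therefore stand beside those of cells with at least 13000 UMIs in both libraries, a comparison chosen after the data were seen.

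Mettl3 (chromosome 14, 52294841 to 52305128, minus strand, mm10) was lower in Mettl3pKO over the epithelial cells but still present. Over all epithelial cells it stood at 13.04 CPM (95% interval 12.1 to 14.0) in WT and 8.18 CPM (7.42 to 8.99) in Mettl3pKO, a ratio of 0.627 (0.556 to 0.708). The ratio was 0.774 (0.652 to 0.919) in acinar-like cells and 0.675 (0.523 to 0.864) in duct and trunk-like cells. It was 0.698 (0.419 to 1.13) in alpha-like cells and 0.699 (0.434 to 1.10) in beta-like cells. In the last pair of classes a difference was not detectable at this depth. The ratio over all epithelial cells was lower than that of each of these classes. Acinar-like cells held the least Mettl3 of these classes in WT (9.36 CPM, against 17.7 in duct and trunk-like cells). They were 43.9% of epithelial cells in WT and 73.9% in Mettl3pKO, so the ratio over all epithelial cells also holds this change of mix. In classes outside the epithelium, where the labels place no deletion, the ratio was 0.802 (0.576 to 1.10) in mesenchyme-like cells, 0.937 (0.496 to 1.76) in immune cells, 1.62 (0.923 to 2.83) in mesothelium-like cells and 0.333 (0.125 to 0.761) in erythroid-like cells. The labels do not name the deleted exons, and reads outside the deleted part check nothing about it, so that these counts do not measure how complete the deletion was. Among acinar-like cells with a UMI of a Y-linked gene and none of Xist, the ratio was 1.12.

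The series title names the endocrine progenitor pool. Progenitor-like, precursor-like and delta-like cells were the scarcest of the 7 epithelial classes in both libraries, and had the lowest Mettl3pKO/WT ratios of shares. Endocrine progenitor-like cells, marked by Neurog3, made up 202 of 4233 epithelial cells in WT (4.77%, 4.15 to 5.46) and 10 of 2876 in Mettl3pKO (0.348%, 0.167 to 0.639), a share 13.7 times higher in WT (7.31 to 29.1). Fev precursor-like cells, the step after the progenitor, numbered 102 in WT and 2 in Mettl3pKO, a share 34.7 times higher in WT (9.35 to 290). Fev UMIs fell less: they stood at 0.297 times WT (0.276 to 0.319) over all epithelial cells and at 0.388 times over every kept cell (0.521 times in cells with 13000 UMIs or more), sums that hold the Fev of other classes and were chosen after the data were seen. Delta-like cells, which make somatostatin, numbered 95 and 3, a share 21.5 times higher in WT (7.14 to 106). Sst UMIs stood at 0.0345 times WT over all epithelial cells and at 0.0640 times over every kept cell; unnamed clusters held 1449 of the 3790 in Mettl3pKO and 32 of the 66679 in WT. Progenitor-like and precursor-like cells together were 7.18% of WT and 0.417% of Mettl3pKO epithelial cells. These classes were shallow and the WT table reaches shallower cells: of endocrine progenitor-like cells, 7.92% in WT and 70.0% in Mettl3pKO had 13000 UMIs or more. Among cells above that floor, 24 of 1661 WT epithelial cells (1.44%) and 8 of 2479 in Mettl3pKO (0.323%) were progenitor-like or precursor-like, a share 4.48 times higher in WT (1.95 to 11.5). Fev precursor-like cells above it numbered 8 and 1, a share 11.9 times higher in WT (1.60 to 530), and delta-like cells 8 and 2. As a Mettl3pKO/WT ratio, the progenitor-like and precursor-like share was 0.0581. It was 0.104 with finer clusters and 0.122 where each cell took the class of its own markers. It was 0.150 with a stricter filter of at least 500 genes and at most 10% mitochondrial UMIs per cell. That filter falls unequally on the libraries. The 90th percentile of the mitochondrial share was 9.97% in WT and 13.3% in Mettl3pKO, where the median was 9.41%.

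Alpha-like and beta-like cells, the glucagon and insulin makers, were also a smaller part of the Mettl3pKO epithelium, at 10.6% against 17.0% in WT. Alpha-like cells were 7.58% of WT and 4.76% of Mettl3pKO epithelial cells (ratio 0.628, 0.510 to 0.770) and beta-like cells 9.38% and 5.88% (0.627, 0.520 to 0.752). With the stricter filter both ratios turned, to 1.06 for alpha-like and 1.49 for beta-like cells, and the beta-like one was 0.964 with no filter and 0.984 with variable genes chosen per library. Acinar-like cells, the makers of digestive enzymes, filled the larger part of the Mettl3pKO epithelium: 1859 of 4233 in WT (43.9%, 42.4 to 45.4) and 2125 of 2876 in Mettl3pKO (73.9%, 72.2 to 75.5). Duct and trunk-like cells, where the bipotent trunk progenitors are found, were 29.7% (28.3 to 31.1) in WT and 15.0% (13.7 to 16.3) in Mettl3pKO. Outside the epithelium, mesenchyme-like cells were 19.5% of all WT cells and 7.62% of all Mettl3pKO cells, but 5.34% and 5.53% of cells with 13000 UMIs or more. Clusters left unnamed for their high doublet scores held 33 WT cells (0.547%) and 236 Mettl3pKO cells (6.52%). By markers, 15 WT and 51 Mettl3pKO cells of these scored best as alpha, and 18 and 185 as duct and trunk. The alpha-like and duct and trunk-like shares above leave them out, by a threshold set after the values were seen.

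**Figure D1:**
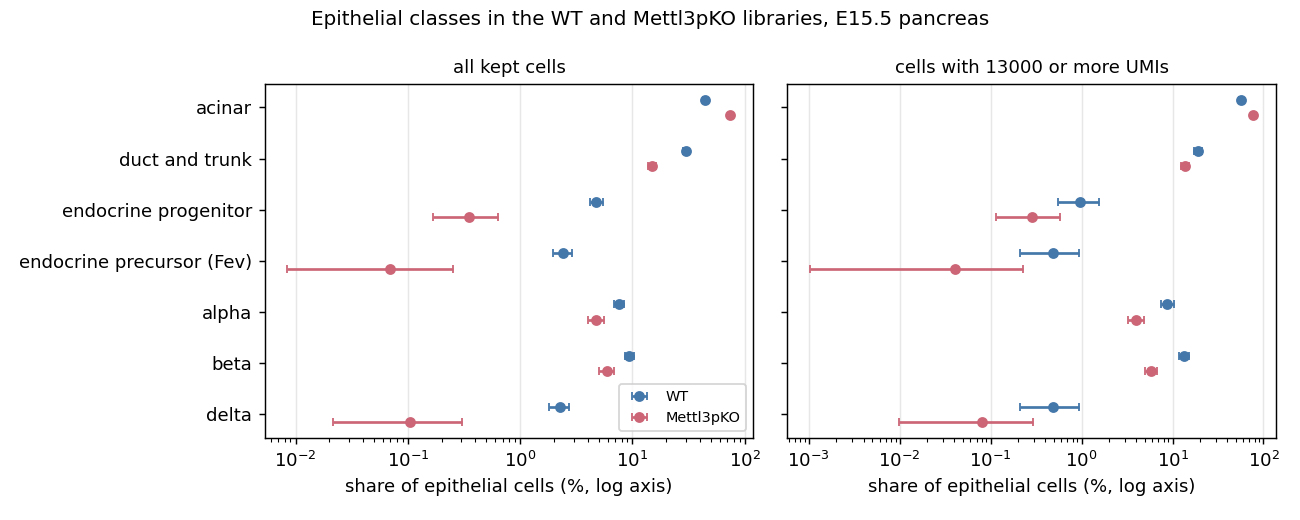
Share of epithelial cells in percent (log axis) held by each of 7 classes in WT (blue) and Mettl3pKO (red), for all kept cells in the left panel and for cells with 13000 UMIs or more in the right panel; points are shares and bars exact Clopper-Pearson 95% intervals. Endocrine progenitor-like cells lie at 4.77% in WT and 0.348% in Mettl3pKO on the left, and acinar-like cells at 43.9% and 73.9%.

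The libraries also differed in their mix of cells with female and male transcripts, so the class shares were taken again in each kind of cell, a split chosen after the data were seen. Among epithelial cells with a Y-linked UMI and none of Xist, the acinar-like share was 15.6% (13.5 to 17.9) in WT and 69.4% (67.1 to 71.6) in Mettl3pKO. Among cells with an Xist UMI and none of the Y-linked genes, it was 56.5% (54.5 to 58.5) in WT and 77.8% (74.1 to 81.2) in Mettl3pKO. The acinar-like share was thus higher in Mettl3pKO in both kinds of cell, at 4.44 and 1.38 times WT. Progenitor-like and precursor-like cells stayed scarce in both: 105 of 1106 WT cells (9.49%) and 9 of 1591 Mettl3pKO cells (0.566%) with a Y-linked UMI, and 147 of 2418 (6.08%) and 2 of 559 (0.358%) with an Xist UMI. Alpha-like and beta-like cells together were 30.1% and 13.1% of the first kind and 11.5% and 9.48% of the second.

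Neurog3 (chromosome 10, 62133090 to 62134763, plus strand), the transcription factor that starts the endocrine programme, was lower in Mettl3pKO when summed over the 7 epithelial classes. Over all epithelial cells it stood at 344 CPM (339 to 349) in WT and 21.3 CPM (20.03 to 22.5) in Mettl3pKO, a ratio of 0.0617 (0.0581 to 0.0656). The ratio was 0.174 in cells with 13000 UMIs or more. Summed over every kept cell whatever its cluster, unnamed clusters included, it was 0.0747 (0.0705 to 0.0790), and 0.192 (0.178 to 0.207) in cells with 13000 UMIs or more, a sum chosen after the data were seen. After thinning to 7812 UMIs per cell, 415 of 3809 WT epithelial cells (10.9%, 9.92 to 11.9) and 36 of 2876 in Mettl3pKO (1.25%, 0.878 to 1.73) had a Neurog3 UMI. A further 424 WT cells were too shallow and were left out, and without thinning the shares were 13.9% and 1.95%. Neurog3 UMIs were also found outside the epithelium, and free RNA, doublets and misassigned cells were not separated as their source. In mesenchyme-like cells, with median depths of 8897 UMIs in WT and 13431 in Mettl3pKO, the thinned share was 19 of 856 in WT (2.22%) and 0 of 276 in Mettl3pKO, which allows a share of up to 1.09%. The Mettl3pKO/WT ratio of the thinned shares was 0.115, and 0.187 with the stricter filter, whereas cells with 3 or more Neurog3 UMIs were 319 of the WT (7.54%) and 16 of the Mettl3pKO epithelial cells (0.556%).

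**Figure D2:**
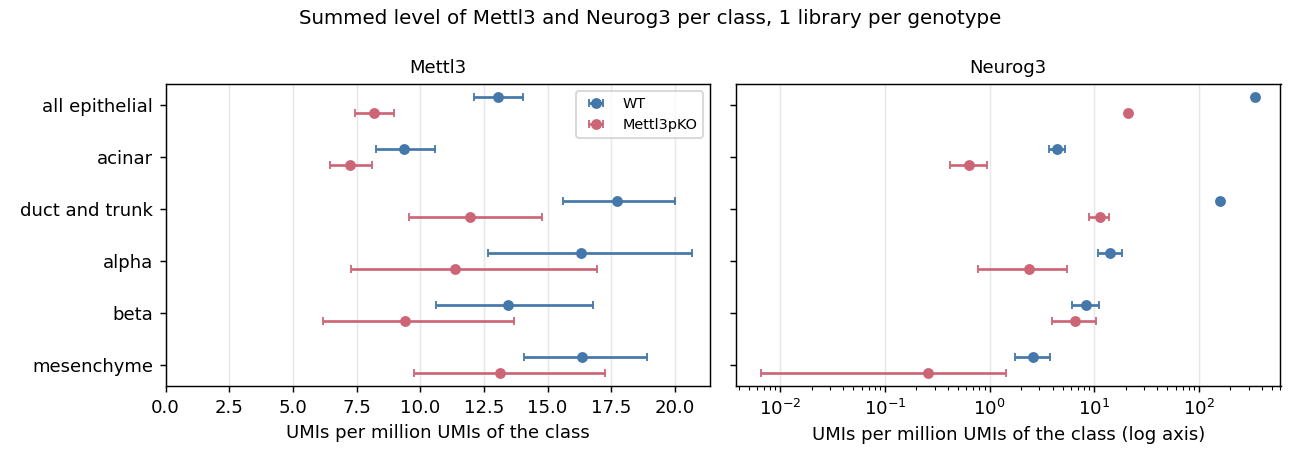
UMIs of Mettl3 (linear axis from 0) and of Neurog3 (log axis) per 1000000 UMIs of the class, in all epithelial cells and in acinar-like, duct and trunk-like, alpha-like, beta-like and mesenchyme-like cells of WT (blue) and Mettl3pKO (red); points are levels and bars exact Poisson 95% intervals. Over all epithelial cells Mettl3 lies at 13.04 in WT and 8.18 in Mettl3pKO, and Neurog3 at 344 and 21.3.

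In acinar-like cells of Mettl3pKO the 12 lowest genes included trypsinogens and carboxypeptidase B, and the highest were 2 serpins. Prss1, a trypsinogen, was 18.8 times higher in WT (17.7 to 20.04; 525 CPM in WT, 27.9 in Mettl3pKO). Cpb1, carboxypeptidase B, was 9.41 times higher in WT (9.23 to 9.59; 2929 and 311 CPM). Also among the lowest were the trypsinogens Prss3 (13.4 times higher in WT), Gm5771, Gm10334, Try10, Try5 and 2210010C04Rik. The others were the trypsin inhibitor Spink1 (5.86 times), the zymogen granule protein Zg16 (3.96 times, and 2.51 times in cells with 13000 UMIs or more), the linker histone gene Hist1h1c (3.64 times) and Gc, vitamin D binding protein (3.45 times). With the stricter filter Prss1 stood at 0.102 times, Prss3 at 0.145 times, Cpb1 at 0.191 times and Spink1 at 0.286 times WT. The trypsinogens are close paralogs whose reads can be shared, so that their separate values are uncertain. The serpins were Serpina10 at 4.45 times WT (4.19 to 4.73) and Serpina6, the corticosteroid carrier, at 3.76 times (3.73 to 3.79; 2719 and 10235 CPM). They were followed by Ckap4 (3.23 times), the acyl-CoA hydrolase Acot1 (2.90 times) and Nxt1 (2.65 times). The other 7 were the m6A reader Ythdf2 (2.64 times, 2.499 to 2.78), Selenop (2.60 times), the p53 target Trp53inp1 (2.41 times), Gm26917, Pgpep1, the immediate early gene Klf6 (2.34 times) and Arf6 (2.30 times). The 2 libraries filled this class largely from different clusters. Of WT acinar-like cells 26.5% lay in the cluster led by Gm10334, Prss3, Prss1, Cpb1 and Zg16, against 1.74% in Mettl3pKO. WT cells of that cluster had a median of 10682 UMIs, under the lowest total of 10719 in Mettl3pKO. These cluster shares are of all kept cells, so that depth may account for a part of them. Of Mettl3pKO acinar-like cells 31.4% lay in the cluster led by Serpina6 and Serpina10, against 3.44% in WT. A cluster led by the cycling genes Ube2c and Plk1 held 34.0%, against 6.35% in WT. Other clusters were closer. The one led by the S-phase genes Rrm2 and Cdc6 held 13.4% in Mettl3pKO and 10.1% in WT, and one led by Gm26917 held 11.6% and 11.5%. All 24 genes kept their direction among cells with a Y-linked UMI and among cells with an Xist UMI.

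By gene group, digestive enzymes were lower in acinar-like cells of Mettl3pKO while few of their transcription factors were. Of 30 enzymes measured, 21 were at least 1.5-fold lower and 1 higher, with a median log2 ratio of -0.98, below all 10000 matched lists. The highly expressed chymotrypsinogen Ctrb1 stood at 51982 CPM in WT and 28353 in Mettl3pKO. Of 11 acinar transcription factors, 1 was lower and 0 were higher (median 0.22, percentile 93.7, and 0.14 in cells with 13000 UMIs or more): Rbpjl stood at 0.548 times WT, and Ptf1a, which drives the acinar programme, at 1.42 times. The multipotent and trunk progenitor list had 6 of 17 members higher and 2 lower (median 0.47, percentile 99.4), with Nkx6-1 at 1.82 times and Sox9 at 1.77 times WT and Mnx1 at 0.382 times. FGF and ERK signalling genes were higher, 9 of 17 against 1 lower (median 0.63, percentile 99.9), among them the ERK-induced factor Etv4 at 4.62 times and the receptor Fgfr1 at 2.71 times. Of 24 p53 targets and apoptosis genes 15 were higher and 0 lower (median 0.92, percentile 100), led by Phlda3 at 3.31 times, Gdf15 at 2.92 times and Tnfrsf10b at 2.68 times. Of 52 G2M genes 16 were higher and 0 lower (median 0.43, percentile 100), and of 42 S-phase genes 8 were higher and 0 lower (median 0.27, percentile 91.1, within the range of matched lists). In cells with 13000 UMIs or more these medians were 0.19 and 0.035. The median over all genes measured in this class was 0.17. Signs of RNA quality went the same way, with 10 of 13 mitochondrial transcripts higher (median 0.73) and 14 of 27 dissociation stress genes higher (median 0.59), among them Hspa1b at 3.34 times and Zfp36 at 2.12 times. Transcripts of islet cells were lower, with all 8 islet hormones measured at least 1.5-fold lower (median -1.12). That median was -0.55 with the stricter filter and -0.10 where WT cells were clustered alone. The endocrine transcription factor and secretory lists had medians of -0.85 and -1.04, which turned to 0.45 and 0.15 with the stricter filter and to 0.28 and 0.19 where WT cells were clustered alone. Without the top 5% of doublet scores the first turned to 0.17.

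**Figure D3:**
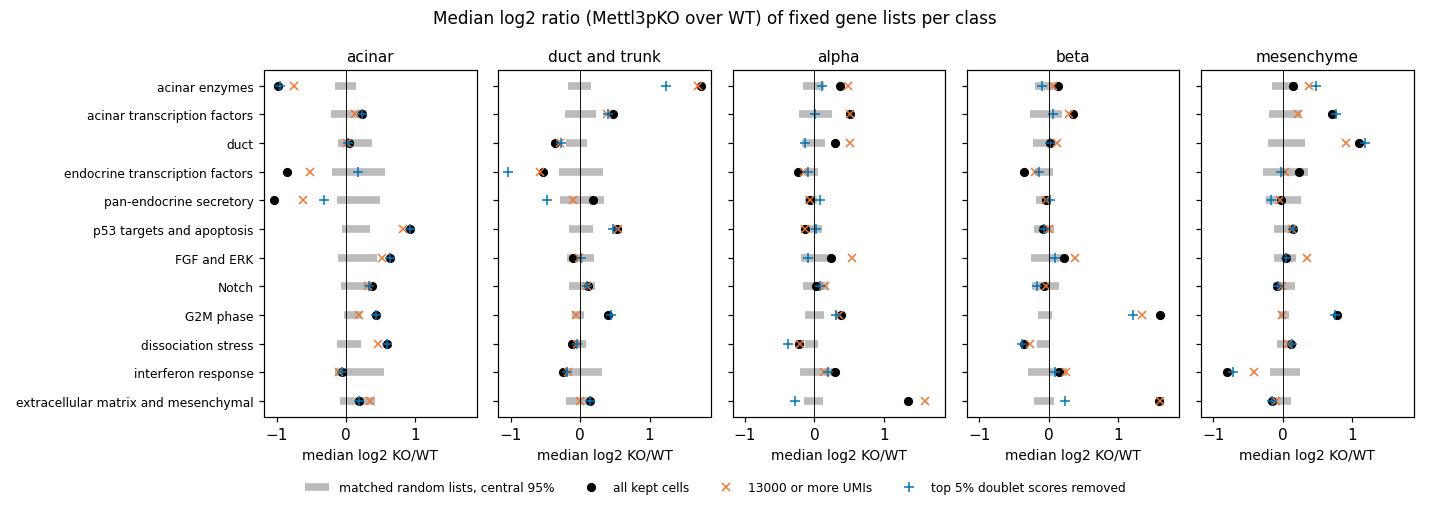
Median log2 ratio of Mettl3pKO to WT (horizontal axis) for 12 gene lists in 5 classes, for all kept cells (black dots), cells with 13000 UMIs or more (orange crosses) and cells left after removing the top 5% of doublet scores (blue plus signs); grey bars give the central 95% of 10000 random lists matched on expression level. Acinar enzymes lie at -0.98 in acinar-like cells and at 1.74 in duct and trunk-like cells.

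Duct and trunk-like cells of Mettl3pKO held little Neurog3 and more of the progenitor factors Onecut2 and Sox11. Neurog3 was 14.2 times higher in WT (11.4 to 18.0; 160 and 11.3 CPM). Of its WT UMIs 83.7% came from 1 cluster, led by Fgfr3, Tinagl1, Dcdc2a and Ces1d, that held 406 WT and 10 Mettl3pKO cells. WT cells of that cluster had a median of 9731.5 UMIs, under the lowest total of 10719 in Mettl3pKO. Of the 81 Neurog3 UMIs in Mettl3pKO 69 lay in the cluster led by Onecut2. Only 11 of 430 Mettl3pKO cells of this class held a Neurog3 UMI without thinning. After Neurog3, the lowest genes were the carboxylesterase Ces1d (5.25 times higher in WT), Ambp (3.49 times), Enpp2 (3.46 times), S100b, Ttyh1, S100a1, Aldoc, Rbmx, 4931406C07Rik, Gsta3 and Slc38a4 (2.29 times). Among the 12 highest, Onecut2 stood at 5.90 times WT (5.30 to 6.57; 31.2 and 184 CPM), Sox11 at 3.83 times, the DNA repair exonuclease Exo1 at 3.18 times, Aldh1b1, an enzyme of pancreatic progenitors, at 2.85 times and Ifitm3 at 2.79 times. The other 7 were abundant in acinar-like cells: Serpina6 (21.5 times WT, and 13.1 times in cells with 13000 UMIs or more), the sulfotransferase Chst2 (9.34 times), Selenop (5.85 times), the acinar factor Rbpjl (5.16 times), Nupr1 (4.29 times), Asns (3.24 times) and Sel1l (3.04 times). Aldh1b1 and Ifitm3 were also higher in acinar-like cells: in Mettl3pKO duct and trunk-like cells they stood at 40.5% and 38.3% of their acinar-like levels. Whether RNA of acinar-like cells gave a part of their rise was not tested. With Scrublet-marked cells kept Serpina6 stood at 7.32 times, Chst2 at 4.97 times, Selenop at 1.74 times, Rbpjl at 1.98 times, Nupr1 at 1.82 times, Asns at 2.02 times and Sel1l at 1.68 times WT, and with the stricter filter Serpina6 at 8.87 times, Rbpjl at 2.20 times and Nupr1 at 1.54 times. Of 11 acinar transcription factors 5 were higher and 0 lower (median 0.48, percentile 100), with Ptf1a at 14.6 times WT (11.3 to 19.1; 4.56 and 66.4 CPM) and Bhlha15 at 4.97 times. Several of these transcripts stood near a like part of their acinar-like level: in Mettl3pKO duct and trunk-like cells Serpina6 stood at 17.1% of its acinar-like level, Chst2 at 17.9%, Rbpjl at 18.8%, Ptf1a at 20.2% and the enzyme Ctrb1 at 15.9%. In Mettl3pKO immune cells they stood at 15.2%, 19.3%, 18.5%, 18.9% and 17.5%, genes chosen after their values were seen. Others stood apart in those immune cells, with Cpa1 at 7.87%, Nupr1 at 10.4% and Selenop at 33.7% (73.7% in WT immune cells). Alpha-like, beta-like and mesenchyme-like cells of Mettl3pKO held less. There Serpina6 stood at 2.45%, 1.99% and 1.88% of its acinar-like level and Ctrb1 at 3.52%, 3.07% and 2.25%. In WT duct and trunk-like cells Ptf1a stood at 1.97% and Ctrb1 at 2.04% of the acinar-like level. Onecut2 leads the cluster that held 31.4% of Mettl3pKO and 4.61% of WT cells of this class, and Ttyh1 and Aldoc are among the leaders of the one that held 10.5% and 33.7%. WT cells of these clusters had medians of 9293 and 9576.5 UMIs, both under the lowest Mettl3pKO total, and the shares are of all kept cells. With the stricter filter the ratio of Neurog3 in this class turned to 1.22, and it was 0.690 where WT cells were clustered alone.

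Gene groups in duct and trunk-like cells of Mettl3pKO showed lower duct genes and higher p53 and unfolded protein lists, while the medians of both endocrine lists changed direction with the processing. Of 21 duct genes 8 were lower and 1 higher (median -0.36, percentile 0), with the water channel Aqp1 at 0.283 times WT and the fibrocystin gene Pkhd1 at 0.425 times. Of 18 endocrine transcription factors 9 were lower and 0 higher (median -0.54, percentile 0.11), among them Isl1 at 0.286 times and Insm1 at 0.355 times WT (0.156 and 0.210 times in cells with 13000 UMIs or more). With the stricter filter that median turned to 0.06, Insm1 to 1.65 times and Dll1 to 1.19 times WT, and the median was also 0.06 among cells with a Y-linked UMI. Of 16 endocrine secretory genes 6 were higher and 1 lower (median 0.18, percentile 85.05). The median of this list turned to -0.10 in cells with 13000 UMIs or more, to -0.48 without the top 5% of doublet scores and to -0.91 with Scrublet-marked cells kept. In the Notch list, whose signal holds back Neurog3 in the trunk, 1 of 21 members was higher and 2 were lower (median 0.11, percentile 82.3): Lfng stood at 2.28 times, the ligand Dll1 at 0.580 times and the receptor Notch1 at 0.692 times WT. Of 23 p53 and apoptosis genes 11 were higher and 0 lower (median 0.53, percentile 100), with Eda2r at 5.74 times and Pmaip1 at 2.76 times. The unfolded protein and integrated stress response list had 8 of 23 members higher and 1 lower (median 0.33, percentile 100), with Edem1 at 2.25 times and Xbp1 at 2.06 times; that median was 0.039 with the stricter filter. Of this list, Asns, Sel1l and Xbp1 in Mettl3pKO stood at 25.9%, 24.5% and 27.1% of their acinar-like levels, and at 22.7%, 25.5% and 32.4% in immune cells. Acinar enzyme transcripts were higher in 22 of 27 cases and lower in 2 (median 1.74). That median was 0.18 with the stricter filter, 0.15 with Scrublet-marked cells kept and 0.18 where WT cells were clustered alone.

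Alpha-like cells kept their main hormone: Gcg, glucagon, stood at 79574 CPM in WT and 91362 in Mettl3pKO. Of 8 islet hormones 5 were lower there and 0 higher (median -0.60, but -0.090 without the top 5% of doublet scores and -0.19 where WT cells were clustered alone), with Sst, somatostatin, 18.7 times higher in WT (12.1 to 30.4; 186 and 9.96 CPM; 7.21 times in cells with 13000 UMIs or more), Ghrl, ghrelin, 4.61 times (4.32 to 4.93; 2177 and 472 CPM), Gast, gastrin, 2.17 times and Pyy 1.53 times (8245 and 5391 CPM). With the stricter filter Sst stood at 0.828 times WT. Sst and Ghrl were also among the hormones farthest below WT in acinar-like and duct and trunk-like cells. Over every kept cell Sst stood at 0.0640 times WT. Whether these differences lay in alpha-like cells or in RNA of other cells was not tested. Other low genes were Parm1 (2.13 times higher in WT), Ins2 (1.81 times, and 3.004 times in cells with 13000 UMIs or more, but 2.49 times WT in Mettl3pKO without the top 5% of doublet scores) and the immediate early genes Arc (1.92 times), Jun (1.55 times), Dusp5 (1.54 times), Fosb and Ier2 (both 1.52 times). Of 20 endocrine transcription factors 3 were lower and 0 higher (median -0.23, percentile 0.01), with Neurog3 at 0.168 times (0.347 times in cells with 13000 UMIs or more) and Mlxipl at 0.641 times WT. That median was -0.15 in cells with 13000 UMIs or more, and within the range of matched lists at -0.11 with Scrublet-marked cells kept and -0.086 without the top 5% of doublet scores. The secretory list stayed near the middle (1 of 21 higher, 2 lower, median -0.07, percentile 41.5), with Chga at 1.57 times and Pcsk1 at 0.483 times. The highest genes were Serpina6 (12.7 times WT), the collagens Col1a1 (10.2 times), Col3a1, Col6a2 and Col6a1, Igfbp4, Ptn, H19, Fstl1, Itm2a, Mest and Sparc (5.24 times). Serpina6 stood at 2.45% of its acinar-like level in Mettl3pKO, beside the enzyme Ctrb1 at 3.52%, and at 0.723% and 1.14% in WT. Mesenchymal transcripts moved together: 16 of 22 matrix genes were higher (median 1.35). Without the top 5% of doublet scores that median was -0.29, and of the 12 highest genes all but Serpina6 (7.09 times, but 24.4 times where WT cells were clustered alone and 44.4 times with the stricter filter) and Igfbp4 (1.31 times) stood below WT, with Col1a1 at 0.742 times.

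Beta-like cells of Mettl3pKO more often held cell cycle transcripts, while insulin was at a like level (Ins2 71858 CPM in WT, 83274 in Mettl3pKO). Of 384 WT cells 26 (6.77%, 4.47 to 9.76), and of 169 Mettl3pKO cells 36 (21.3%, 15.4 to 28.3), were proliferating after thinning, a ratio of 3.15 (1.85 to 5.43), with 13 WT cells left out. Without thinning the shares were 10.1% and 34.3%. In cells with 13000 UMIs or more the ratio was 2.48 (1.40 to 4.51). Of 52 G2M genes 43 were higher and 0 lower (median 1.60, percentile 100), with Cenpf at 9.06 times and Bub1 at 6.73 times WT. Of 42 S-phase genes 30 were higher and 0 lower (median 0.89), and the G2M median was 0.79 with Scrublet-marked cells kept. The summed UMIs differed less, at 1.70 times WT (1.65 to 1.76) for the G2M list and 1.62 times for the S-phase list. Ube2c (4.57 times WT), the cell cycle inhibitor Cdkn1c (3.93 times), Top2a (3.70 times), Stmn1 (3.48 times) and Lgi2 (2.75 times) were among the 12 highest genes, beside Serpina6 (10.8 times), Col1a1, Itm2a, Sparc, Col1a2, Col3a1 and H19. Here Serpina6 stood at 1.99% and Ctrb1 at 3.07% of the acinar-like level in Mettl3pKO, and at 0.693% and 1.49% in WT. The matrix list had a median of 1.59, and of 0.24 without the top 5% of doublet scores, where Itm2a stood at 0.806 times, Cdkn1c at 1.05 times and Ube2c at 2.93 times WT. Among the 12 lowest, Zfp423 was 2.16 times higher in WT, the microtubule protein gene Mapt 2.06 times and the retinol carrier Rbp4 1.62 times, beside Rab3b and the imprinted genes Meg3 and Peg10. Peg10 turned to 1.18 times WT with the stricter filter. The other low genes were the immediate early genes Atf3 (2.13 times higher in WT), Nr4a1 (2.00 times; 462 and 231 CPM), Arc, Klf4, Dusp5 and Junb. In all, 8 of 27 dissociation stress genes were lower and 0 higher (median -0.35, percentile 0). Of 21 endocrine transcription factors 5 were lower and 1 higher (median -0.35, percentile 0, and -0.19 in cells with 13000 UMIs or more), with Pax4 at 0.166 times WT (0.317 times in those cells, and 0.417 times without the top 5% of doublet scores). With Scrublet-marked cells kept, and without the top 5% of doublet scores, that median was -0.14, within the range of matched lists. Of the secretory list, 0 of 21 members passed 1.5-fold either way.

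Acinar-like and duct and trunk-like cells also held more proliferating cells in Mettl3pKO, by ratios of 1.25 (1.16 to 1.35) and 1.53 (1.34 to 1.75). Among cells with 13000 UMIs or more the ratios were 1.13 (1.03 to 1.24) and 1.11 (0.932 to 1.32), so that a difference was not detectable in duct and trunk-like cells there. In these, the medians of the G2M and S-phase lists turned from 0.40 to -0.054 and from 0.11 to -0.19 at that floor, and the summed G2M UMIs stood at 0.944 times WT (0.933 to 0.955). The thinned shares were 60.3% in WT and 75.5% in Mettl3pKO for acinar-like cells (66.5% and 85.6% without thinning; 135 WT cells left out). They were 53.4% and 81.9% for duct and trunk-like cells (54.2% and 90.0%; 147 left out), 48.9% and 76.1% for mesenchyme-like cells (46.4% and 85.9%; 319 left out) and 4.61% and 10.2% for alpha-like cells (8.72% and 17.5%; 17 left out). In alpha-like cells the ratio was 2.22 (0.981 to 5.02), and 1.47 (0.519 to 4.19) at that floor, so that a difference was not detectable. At that floor the mesenchyme-like ratio was 1.04, against 1.55 for all kept cells, and that of mesothelium-like cells turned from 1.90 to 0.917.

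Mesenchyme-like cells lie where the labels place no deletion, but the class also held epithelial transcripts and is not a clean comparison of undeleted cells. Serpina6 and the enzyme Ctrb1 stood at 1.88% and 2.25% of their acinar-like levels in Mettl3pKO and at 0.555% and 0.986% in WT. Apart from Serpina6, at 12.7 times WT, the 12 highest genes were Mgp (2.27 times) and the cell cycle genes Tk1 (2.24 times), Aurkb (2.23 times), Kif20b, Ncaph, Rrm2, Ncapg, Knl1, Top2a, Ccna2 and Pclaf (1.98 times). In cells with 13000 UMIs or more Tk1 stood at 1.35 times, Aurkb at 1.29 times and Pclaf at 1.24 times WT. Of 52 G2M genes 43 were higher (median 0.77), and the median was -0.01 in cells with 13000 UMIs or more. The cluster led by the cycling genes Anln, Nusap1 and Top2a held 23.1% of WT and 53.6% of Mettl3pKO cells of this class. The 12 lowest were the protocadherin-like Fat4 (1.795 times higher in WT), Htra1 (1.77 times), the matrix genes Col23a1 (1.73 times), Sned1 and Col6a6, Nrbp2, Npr3, Kdm5b, Ifitm1, Kcnq1ot1, Peg10 and Meg3 (1.44 times). Interferon response genes were lower in 13 of 20 cases and higher in 0 (median -0.81, percentile 0, and -0.42 in those cells), with Ifit1 at 0.0251 times (0.583 times in cells with 13000 UMIs or more) and Rsad2 at 0.118 times WT. Without a cluster of 17 WT cells led by Ifit1 and Ifit3, 7 of 20 were lower (median -0.46). Of 22 p53 and apoptosis genes 2 were higher and 0 lower (median 0.14). Epithelial adhesion genes, markers of epithelial cells, were higher in 13 of 16 cases (median 1.501), led by Cldn3 at 6.06 times and Epcam at 3.43 times WT. The median was 3.69 where WT cells were clustered alone.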

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

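The common floor of 13000 UMIs, the splits by sex-linked genes and the sums over every kept cell were chosen after the class shares were seen. What each test should give was set down before its own result, except for the sums over every kept cell and for the acinar genes in cells split by sex-linked genes.

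Transcripts of both sexes were found in both libraries, in data outside the comparisons planned. After thinning, 56.6% of WT cells and 20.02% of Mettl3pKO cells had an Xist UMI, and 27.7% of WT and 43.3% of Mettl3pKO cells a UMI of a Y-linked gene, so that each library held cells of female and of male embryos in another mix. In cells split without thinning, the acinar-like share of epithelial cells differed between the kinds of cell in WT. It was 15.6% among WT cells with a Y-linked UMI and no Xist UMI and 56.5% among WT cells with an Xist UMI and no Y-linked UMI, against 69.4% and 77.8% in Mettl3pKO. No test was made of these differences, and the labels do not say how many embryos each library pooled. A further signal was in classes that no comparison used: 7 hepatocyte-like and 6 neuron-like cells in WT and 2 neuron-like cells in Mettl3pKO, where 0 of 3622 cells were hepatocyte-like, which allows a share of up to 0.0828%. Clusters left unnamed for high doublet scores held 33 WT and 236 Mettl3pKO cells; of these, 15 and 51 lay in a cluster led by Gcg and 18 and 185 in one led by Fabp7 and Onecut2.

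Endocrine progenitor-like, Fev precursor-like and delta-like cells together were scarce in Mettl3pKO, at 0.522% of epithelial cells against 9.43% in WT; the shallower cells of the WT table may account for part of the size, but not for the whole, since above 13000 UMIs the share was still 4.78 times higher in WT (2.29 to 10.9). Cells hidden in other clusters with WT levels of their marker gene are argued against as the whole cause for progenitor-like and delta-like cells. For progenitor-like cells, Neurog3 above that floor stood at 0.174 times WT over all epithelial cells (0.160 to 0.189). Over every kept cell it stood at 0.192 times (0.178 to 0.207). For delta-like cells, Sst over every kept cell above that floor stood at 0.162 times (0.155 to 0.169). The intervals of these sums cover counting error of UMIs only and not the spread between cells. Above the floor, 143 WT and 45 Mettl3pKO epithelial cells held a Neurog3 UMI without thinning. Neurog3 and Sst mark these classes, so their sums cannot tell fewer cells from hidden cells with less of either transcript. Hidden cells also stay open as a part of the scarcity of delta-like cells, since unnamed clusters held 1446 of the 2697 Mettl3pKO Sst UMIs above the floor. They stay open in full for Fev precursor-like cells, since Fev over every kept cell stood at 0.521 times WT (0.479 to 0.566). This is under the limit of 0.67 used for Neurog3 and Sst, but other classes hold Fev too. The alpha-like and beta-like share there was 0.444 times WT, a stricter limit set after the value was seen. The other mix of female and male cells is argued against by cells with a Y-linked UMI and no Xist UMI alone, where the share was 22.9 times higher in WT (11.7 to 51.0). A lower number of progenitor-like cells in Mettl3pKO may be biological, as a hypothesis from a single library per genotype; that the Mettl3pKO embryos differed in stage, or lost fragile cells in preparation, was not tested and stays open.

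The 24 genes named in acinar-like cells differed by a median log2 ratio of 1.89, each signed by its direction. The checks by depth, cycling and sex-linked genes each used a part of the acinar-like cells in which these genes were chosen. They are thus not independent of that choice and speak only to each explanation as the whole cause. Depth is so argued against, since the median was 1.69 in acinar-like cells with 13000 UMIs or more (interquartile range of the change 0.29). So are cycling cells, since the median was 1.86 among cells with fewer than 2 UMIs of the proliferation genes (0.70). The other mix of female and male cells is argued against as the whole cause as well, since the median was 1.87 among cells with a Y-linked UMI and no Xist UMI (0.52) and 1.94 among cells with an Xist UMI and no Y-linked UMI (0.47). A difference between the libraries in all cells could not be excluded: the median was 0.40 in mesenchyme-like cells, against 1.83 in acinar-like cells for the same 22 genes, which is below the limit set beforehand by less than its interquartile range of 0.78. Mesenchyme-like cells also held acinar transcripts of unknown source (Ctrb1 at 2.25% of its acinar-like level in Mettl3pKO), and whether the lower enzymes may mark younger acinar cells or a loss of m6A was not tested.

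The list of immediate early and other stress genes leaned lower in alpha-like and beta-like cells of Mettl3pKO and higher in acinar-like cells, with list medians of -0.22, -0.35 and 0.59; in alpha-like cells 5 of 27 were 1.5-fold lower and 3 higher. Handling of the whole library would move mesenchyme-like cells as well, where the median of the list was 0.11. The epithelial classes went opposite ways, so that the mesenchyme-like value has no single value to be set against and decides nothing. The mesenchyme-like median was -0.10 among cells with a Y-linked UMI and 0.33 among cells with an Xist UMI, so handling stays open.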

How the results depend on the processing

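Chosen after the data were seen were the common floor of 13000 UMIs, the split by sex-linked genes and, for expression ratios and proliferation, the removal of the top 5% of doublet scores. No paired analysis was possible because each genotype had 1 library, and for the same reason no library could be left out. Values are Mettl3pKO/WT ratios, or log2 medians where so named. The lower share of progenitor-like and precursor-like cells, and the lower Neurog3 level over all epithelial cells, kept their direction under every alternative run. Of 27 medians of a list in a class, each over 11 alternatives, 267 values stayed within the interquartile range of the list's members, 23 moved and 7 turned. A median inside the central 95% of matched lists was not counted as turned: that of the secretory list in alpha-like cells changed sign to 0.10 with Scrublet-marked cells kept. Several medians of other lists that changed sign are given in the report, which may not be all of them. Of class shares, 50 stayed within their interval, 29 moved and 3 turned, and of named single genes 1220, 583 and 33. Over 9 alternatives each, 47 of 47 named genes kept their direction in acinar-like cells, 44 of 47 in duct and trunk-like cells, 20 of 32 in alpha-like cells, 33 of 36 in beta-like cells and 42 of 42 in mesenchyme-like cells. Depth left Mettl3 in alpha-like and beta-like cells with intervals that hold 1 (0.419 to 1.13 and 0.434 to 1.10). The number of cells limits the rare classes, with an interval from 0.167% to 0.639% for 10 endocrine progenitor-like cells in Mettl3pKO. For each value below that moved or turned, the cause was not tested.

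With at least 500 genes and at most 10% mitochondrial UMIs, the shares turned to 1.06 for alpha-like and 1.49 for beta-like cells. They moved to 0.187 for cells with a Neurog3 UMI, 0.150 for progenitor-like and precursor-like cells, 0.684 for all endocrine classes, 1.375 for acinar-like and 0.730 for duct and trunk-like cells. Neurog3 over all epithelial cells moved to 0.110. Medians moved to 0.26 for G2M and 0.46 for mitochondrial genes in acinar-like cells, and to 0.18 for acinar enzymes and 0.27 for Notch in duct and trunk-like cells. Medians turned to 0.0559 for endocrine transcription factors in duct and trunk-like cells and to -0.11 for matrix genes in alpha-like cells. In duct and trunk-like cells Neurog3 turned to 1.22, Insm1 to 1.65 and Dll1 to 1.19. In alpha-like cells Col1a1 turned to 0.785, Col3a1 to 0.806, Col6a2 to 0.645, Col6a1 to 0.813, Igfbp4 to 0.986, Itm2a to 0.815, Ptn to 0.968 and Fstl1 to 0.822, and Peg10 in beta-like cells to 1.18.

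Among cells with 13000 UMIs or more, shares moved to 0.181 for cells with a Neurog3 UMI, 0.223 for progenitor-like and precursor-like, 1.34 for acinar-like, 0.725 for duct and trunk-like, 0.454 for alpha-like, 0.437 for beta-like and 0.168 for delta-like cells, and turned to 1.04 for mesenchyme-like cells. Neurog3 moved to 0.174. Medians moved to 0.19 for G2M and 0.55 for mitochondrial genes in acinar-like cells and to -0.42 for interferon genes in mesenchyme-like cells, where G2M turned to -0.00793. Proliferating shares moved to 1.13 in acinar-like, 1.11 in duct and trunk-like and 1.045 in mesenchyme-like cells and turned to 0.917 in mesothelium-like cells.

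With the top 5% of doublet scores removed, the beta-like share moved to 0.830 and Neurog3 to 0.0666. The median of endocrine transcription factors in alpha-like cells moved to -0.0862 and that of matrix genes in beta-like cells to 0.24, and matrix genes in alpha-like cells turned to -0.29. There Col1a1 turned to 0.742, Col3a1 to 0.942, Col6a2 to 0.637, Col6a1 to 0.719, H19 to 0.911, Itm2a to 0.692, Ptn to 0.305, Fstl1 to 0.688, Mest to 0.586, Sparc to 0.733 and Ins2 to 2.49; in beta-like cells Itm2a turned to 0.806 and Peg10 to 1.09. With Scrublet-marked cells kept, shares moved to 0.438 for duct and trunk-like and 0.836 for beta-like cells. Medians moved to 0.15 for acinar enzymes in duct and trunk-like cells, -0.11 for endocrine transcription factors in alpha-like cells, and 0.79 for G2M and 0.14 for matrix genes in beta-like cells, and turned to -0.25 for matrix genes in alpha-like cells. There Itm2a turned to 0.891, Ptn to 0.724 and Fstl1 to 0.712, and in beta-like cells Sparc to 0.902 and Peg10 to 1.03.

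At Leiden resolution 2.0 the progenitor-like and precursor-like share moved to 0.104 and the beta-like one to 0.867; at 0.5 the latter moved to 0.5075. With variable genes chosen per library, duct and trunk-like cells moved to 0.434 and beta-like cells to 0.984, and with no filter on cells beta-like cells to 0.964. With each cell named by its own markers, progenitor-like and precursor-like cells moved to 0.122 and duct and trunk-like cells to 0.637. With WT clustered alone, medians moved to 0.18 for acinar enzymes in duct and trunk-like cells and to 0.49 for G2M and 3.69 for epithelial adhesion in mesenchyme-like cells. Insm1 turned to 1.36 in duct and trunk-like, Ins2 to 1.36 in alpha-like and Peg10 to 1.575 in beta-like cells.

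Among cells with a Y-linked UMI and no Xist UMI, shares moved to 0.0731 for cells with a Neurog3 UMI, 0.317 for all endocrine classes, 4.44 for acinar-like, 0.411 for duct and trunk-like, 0.437 for alpha-like and 0.432 for beta-like cells. Mettl3 in acinar-like cells turned to 1.12, on 173 WT cells. The median of endocrine transcription factors in duct and trunk-like cells turned to 0.0590; in mesenchyme-like cells interferon genes moved to -0.24, G2M to 0.95, and stress genes turned to -0.10. Among cells with an Xist UMI and no Y-linked UMI, shares moved to 0.175 for cells with a Neurog3 UMI, 0.514 for all endocrine classes, 1.38 for acinar-like, 0.891 for alpha-like and 0.767 for beta-like cells, and Neurog3 to 0.0510. Matrix genes in beta-like cells moved to 0.63, and in mesenchyme-like cells G2M moved to 0.61 and stress genes to 0.33.

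With TMM factors, Mettl3 over all epithelial cells moved to 0.716 and Neurog3 to 0.0705. With the mean of values scaled per cell, Neurog3 moved to 0.0564, G2M in acinar-like cells to 0.65 and in mesenchyme-like cells to 0.96, and with thinned cells Neurog3 moved to 0.0722. Cells with 3 or more Neurog3 UMIs gave a share of 0.0738. Proliferating shares moved to 1.30 in duct and trunk-like cells at 1 or more UMIs and to 1.85 in mesenchyme-like cells without thinning. Of the 24 named genes per class, a floor of 50 CPM kept 14 in acinar-like, 13 in duct and trunk-like, 14 in alpha-like and 12 in beta-like cells; a floor of 200 CPM kept 14, 9, 14 and 14, and 11 in mesenchyme-like cells. Lower and higher floors let in or leave out genes by construction.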

Other observations

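No tests were run for this part. Neurog3 in mesothelium-like cells was singled out after its value was seen, and Gcg and Ctrb1 were set beside it there as markers of other cells. The other genes named are members of the fixed lists farthest from no difference.

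The m6A machinery lists had medians within the range of matched lists in acinar-like cells, where the median over all genes was 0.17, while several members were higher. In acinar-like cells, of 8 writers 3 were at least 1.5-fold higher and 0 lower (median log2 ratio 0.28, percentile 68.6), with Rbm15 at 2.16 times WT, Wtap at 1.73 times and Cbll1 at 1.54 times. Of 13 readers and erasers 3 were higher and 0 lower (median 0.27, percentile 92.2), led by Ythdf2 and followed by Igf2bp1 and Ythdf3 (both at 1.53 times). In alpha-like, beta-like and mesenchyme-like cells the reader and eraser medians were -0.02, -0.11 and -0.04. In duct and trunk-like cells Rbm15 stood at 2.08 times, Wtap at 1.66 times and Ythdf2 at 2.21 times WT. Of the signalling lists in acinar-like cells, Notch and Wnt had medians within the range of matched lists, which reached up to 0.41 and 0.42, and Hippo and YAP lay at its upper end. Of 22 Notch genes 9 were higher and 1 lower (median 0.38, percentile 95.8), with Notch3 at 2.995 times, Notch2 at 2.51 times and Notch4 at 0.301 times WT. Of 20 Wnt genes 8 were higher and 2 lower (median 0.34, percentile 92.3), with Wnt4 at 3.75 times and Ccnd1 at 2.20 times, and Wnt4 also stood at 4.27 times WT in duct and trunk-like cells. Of 16 Hippo and YAP genes 6 were higher and 0 lower (median 0.42, percentile 97.53), with Amotl2 at 2.16 times and Cyr61 at 1.99 times. The cell cycle inhibitor Cdkn1a, a p53 target, stood at 159 CPM in WT and 330 CPM in Mettl3pKO acinar-like cells. Ribosomal protein genes (82 measured, 0 higher, 1 lower, median -0.05) and splicing genes (25 measured, 0 higher, 2 lower, median 0.11) stayed near no difference in that class.

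Among imprinted growth genes, Nnat stood at 0.275 times and Meg3 at 0.536 times WT in acinar-like cells, with 1 of 20 higher and 3 lower there (median 0.02) and 6 of 18 higher and 1 lower in alpha-like cells. The alpha-like median was 0.16, but -0.16 with the stricter filter and -0.12 without the top 5% of doublet scores. The hypoxia-induced carbonic anhydrase Car9 was higher in Mettl3pKO in acinar-like (1.83 times), duct and trunk-like (1.75 times) and mesenchyme-like cells (7.42 times), while the glycolysis and hypoxia list had medians of -0.12 in acinar-like and -0.24 in duct and trunk-like cells. In alpha-like cells S-phase genes were higher in 18 of 34 cases and G2M genes in 13 of 31, with 0 lower in either (medians 0.71 and 0.39, but 0.097 and -0.017 with Scrublet-marked cells kept). Outside the epithelium, endothelium-like cells were 69 of 6034 WT cells (1.14%) and 11 of 3622 Mettl3pKO cells (0.304%), and pericyte-like cells 1.06% and 0.497%, whereas immune cells were 2.22% and 2.21%. Neurog3 in mesothelium-like cells stood at 2.00 CPM in WT (4 UMIs) and 41.3 CPM in Mettl3pKO (51 UMIs), beside markers of other cells: Gcg stood at 117 and 2341 CPM and Ctrb1 at 576 and 5569 CPM in that class.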
